A study of Mus musculus with 2 samples.

How the data were processed

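Gene expression was measured in mouse T cells with 1-colour Affymetrix oligonucleotide arrays, 1 array for control T cells and 1 for T cells that had been exposed to retinal pigment epithelium (RPE), the pigmented cell layer behind the retina. Per the labels' protocols, total RNA was extracted with Trizol, purified on columns, reverse transcribed, and turned into biotin-labelled cRNA by in vitro transcription. The summarization software, its version and any detection calls are not given in the sources used here.

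The deposited values are linear intensities, 1 signal per probe set (a group of short probes for 1 transcript) and array, with no log transformation. Both columns held 45101 probe sets, of which 64 were manufacturer's controls. The mean without the lowest and highest 2% of probe sets was 99.97 on each array, so the deposited intensities had already been brought to a common scale of about 100, and no further scaling was applied in the main setting. Signals ran from 0 to 7196.3 on the control array and to 7804.0 on the RPE-exposed array. The median signal was 15.9 and 16. No column of the table belonged to another sample.

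Gene names came from the platform annotation supplied with the table, which listed 35890 probe sets. Of these, 34958 named exactly 1 gene and 932 named several. The remaining 9160 non-control probe sets had no listed gene here. Gene identifiers of 34754 of the 1-gene probe sets were found in the mouse RefSeq gene table of assembly GRCm38.p6, and no symbol needed updating. Probe sets with no name or several names were kept out of the gene comparisons. The array gives no coordinates and its build is not named, so no genomic positions are printed. Probe set names ending in x mark probes shared with other sequences, and those ending in s mark probes shared by several transcripts.

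From the deposited intensities, log2 signals and their difference, RPE-exposed minus control, were computed per gene with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. A gene was represented by its probe set with the highest mean log2 signal. A floor was set at each array's median over non-control probe sets (15.9 and 16), and signals under it were set to it. Of 18193 genes, 10011 lay above the floor on both arrays, 1004 on 1 array, and 7178 on neither. The 11015 genes above the floor on at least 1 array were compared. For a gene above the floor on 1 array only, the fold is a lower bound, the brighter signal over the other array's floor, and is written as "at least".

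With 1 array per group there was no spread between samples, no test, and no p-value. Genes were counted by a fixed rule of size, a difference of at least 2-fold (1 on the log2 scale). A pair of descriptions of error within this pair of arrays were used. First, where a gene had several probe sets above the floor on both arrays, the pooled SD of their log2 differences was 0.24 over 4779 genes. It was 0.31 at signals under 100, 0.18 at 100 to 500, and 0.10 at 500 or more. Probe sets of 1 gene are not replicates of cells, animals or arrays. Second, each named gene was set beside the central 95% of log2 differences of genes in the same twentieth of mean level, called the like-level range here.

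Before the data were examined, 38 gene lists were fixed from textbook knowledge, covering T-cell subsets, signalling, cell cycle, metabolism, stress, and the other cell types that either sample could hold. Each list's median log2 difference was placed among the medians of 10000 random lists of the same size, with each member replaced by a gene in the same of 20 level bins. A list is said to stand apart where its median lay under the 2.5th or over the 97.5th percentile. Of lists of independently drawn genes 5%, about 1.9 of 38, would do so. Members of a real list can vary together and some lists share genes, so the number expected by chance between 2 cultures is not known. These percentiles describe these 2 arrays and are not tests across replicates. A single simulated pair of arrays was built from the probe-set SDs, with 10755 genes compared. On it the same steps recovered 92.0% of 100 genes changed by 1.5 on the log2 scale and 94.0% of 100 changed by 2.5. They called 3 of 10515 unchanged genes 2-fold different, and put 6 of 100 unshifted lists outside the band. The simulated noise was drawn for each probe set on its own. It held no variation between cultures and no genes that move together, so these rates need not hold for the real pair. A single list shifted by 0.3 came out at percentile 100, and another shifted by -0.3 at percentile 0.

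The rule for the genes named was also fixed before the data were examined. It took every measured member of the Th17, regulatory T-cell, and cathepsin L inhibition and RPE suppression factor lists, the 10 genes highest and the 10 lowest by log2 difference among those above the floor on both arrays, and the 5 largest bounds in each direction. In every other list it took up to 2 members per direction that differed by 2-fold. It named 91 genes. A further 60 genes, given as examples of lists or members of patterns, were chosen after their values were seen. The other settings tried were median centring, quantile normalization, floors at the 25th and 75th percentile or none, the mean of all probe sets of a gene, leaving out probe sets whose names end in x, s or a, an offset of 16 added before the log, thresholds of 1.5-fold and 3-fold, a demand that every probe set of a gene differ by 2-fold the same way, and random lists without matching. No paired or leave-one-out analysis applies to 1 array per group.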

Results

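The series set mouse T cells that had been exposed to RPE against T cells that had not, with 1 array each. The question was how exposure to this ocular epithelium alters T-cell transcripts, those of interleukin-17-producing helper T cells (Th17 cells) in particular. Both samples were labelled as coming from male C57BL/6-background mice 6 weeks old. The control was titled as CD4 T cells. For the exposed sample the title and source named T cells, whereas the tissue field named cultured RPE. There were no replicates, so every value below stands for 1 array, no difference could be compared with a spread between samples, and the number of arrays limits the precision. The 3'/5' signal ratio of the Gapdh control probe sets was 0.80 on both arrays, and that of beta-actin was 1.17 on the control and 1.14 on the exposed array. The manufacturer's control BioB reached at most 1 on the control and 1.1 on the exposed array, under the floor. A probe set of the control BioC gave 297.5 and 269.7.

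The arrays were alike for most genes. Across the 10011 genes above the floor on both arrays, the log2 signals correlated with Pearson's r = 0.986, a correlation across genes, which are not independent replicates, and the median log2 difference was -0.011. Of the 11015 genes compared, 93.1% lay within 1.5-fold. In RPE-exposed T cells 48 genes were at least 2-fold higher and 69 at least 2-fold lower, together 1.06% of those compared. Most were dim, since the brighter signal was 100 or more for only 13 of the higher and 25 of the lower genes. The counts depended on the floor: with it at the 75th percentile of each array, 6 genes were higher and 16 lower, and with no floor 1741 were higher and 1592 lower.

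**Figure D1:**
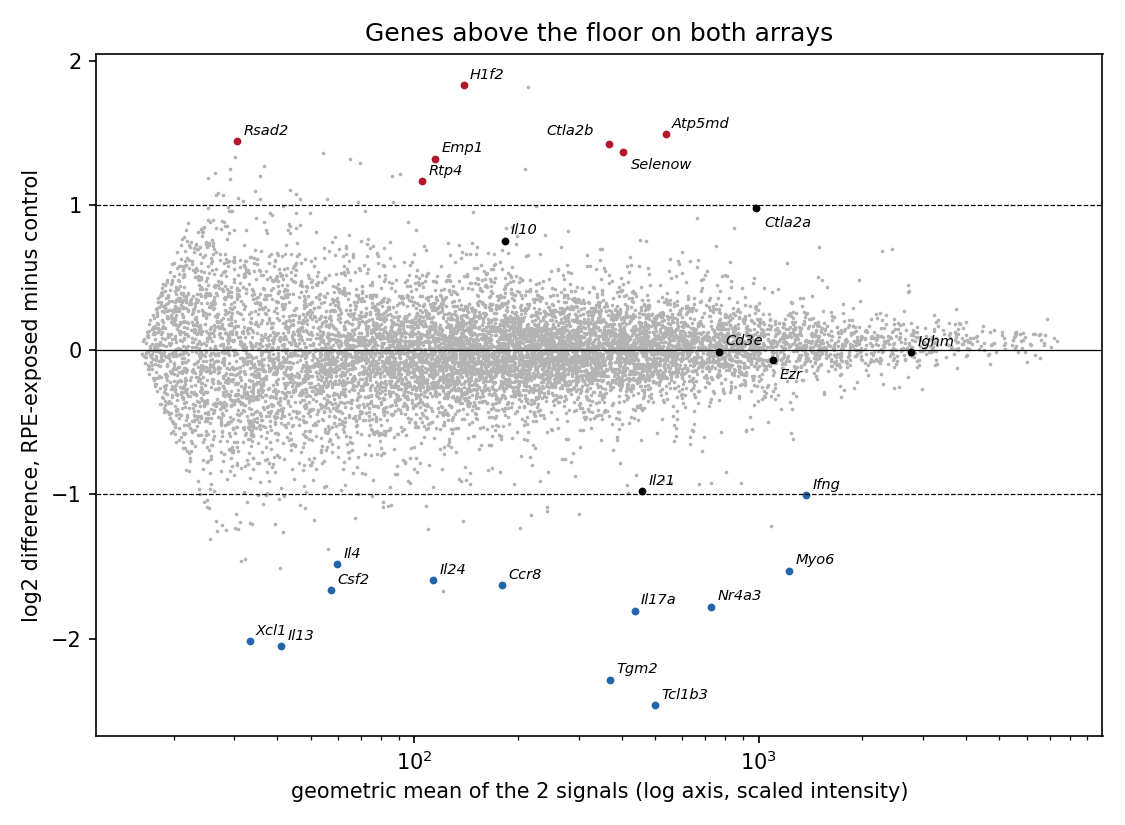
Each grey point is 1 of the 10011 genes above the floor on both arrays, with the geometric mean of its 2 signals on a log axis (scaled intensity) against its log2 difference, RPE-exposed minus control. Dashed lines mark 2-fold, named genes past it are red (higher) or blue (lower), and other named genes are black. Il17a at -1.81 and Tcl1b3 at -2.46 lie far below genes of like level, while Ctla2b lies at 1.43.

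Th17-associated transcripts were lower in RPE-exposed T cells. Il17a, the cytokine that defines these cells, had a signal of 814.9 in control and 233.0 in exposed T cells, 3.50-fold lower (log2 difference -1.81, like-level range -0.48 to 0.44, 1 probe set). Ahr, a ligand-activated transcription factor of Th17 cells, was 2.36-fold lower at 168.1 and 71.2 (-0.89 with the floor at the 75th percentile), and its 2 probe sets gave -1.11 ± 0.18 (SD). Il21, a cytokine made by Th17 and follicular helper cells, was 1.98-fold lower at 645.1 and 326.7 and so just missed 2-fold, with 2 probe sets giving -1.18 ± 0.27 (SD). Irf4, a transcription factor needed for Th17 differentiation, was 1.49-fold lower at 1516.7 and 1015.6.

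Of 13 list members above the floor, 2 were at least 2-fold lower, none was 2-fold higher, and 11 of 13 had a negative difference. The list's median of -0.39 lay at percentile 0.01 of matched random lists, whose central 95% ran from -0.16 to 0.13. Genes of B cells (median -0.54) and of macrophages and dendritic cells (median -0.47) were lower as well, and Irf4, Ahr, Ccr6 and Il6ra are also expressed by such cells. Among the smaller negative differences were Ccr6, the Th17 chemokine receptor (-0.39), Tnfrsf25 (-0.37), Il6ra (-0.28), Stat3 (-0.24) and Batf (-0.04). Rora gave -0.54. All of these lay within their like-level ranges. The 6 probe sets of Rora above the floor, and the 4 of Stat3, disagreed in sign and averaged -0.095 in each gene. Il1r1 had a signal of 26.1 in control cells and was under the floor in exposed cells, at least 1.63-fold lower. Maf (0.36) and Il12rb1 (0.14) had positive differences, and Ccl20 was not above the floor on either array. The 5 probe sets of Maf above the floor on both arrays gave 0.33 ± 0.063 (SD), but the average over all 6 was -0.32. The other 4 listed genes are not analysed here.

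**Figure D2:**
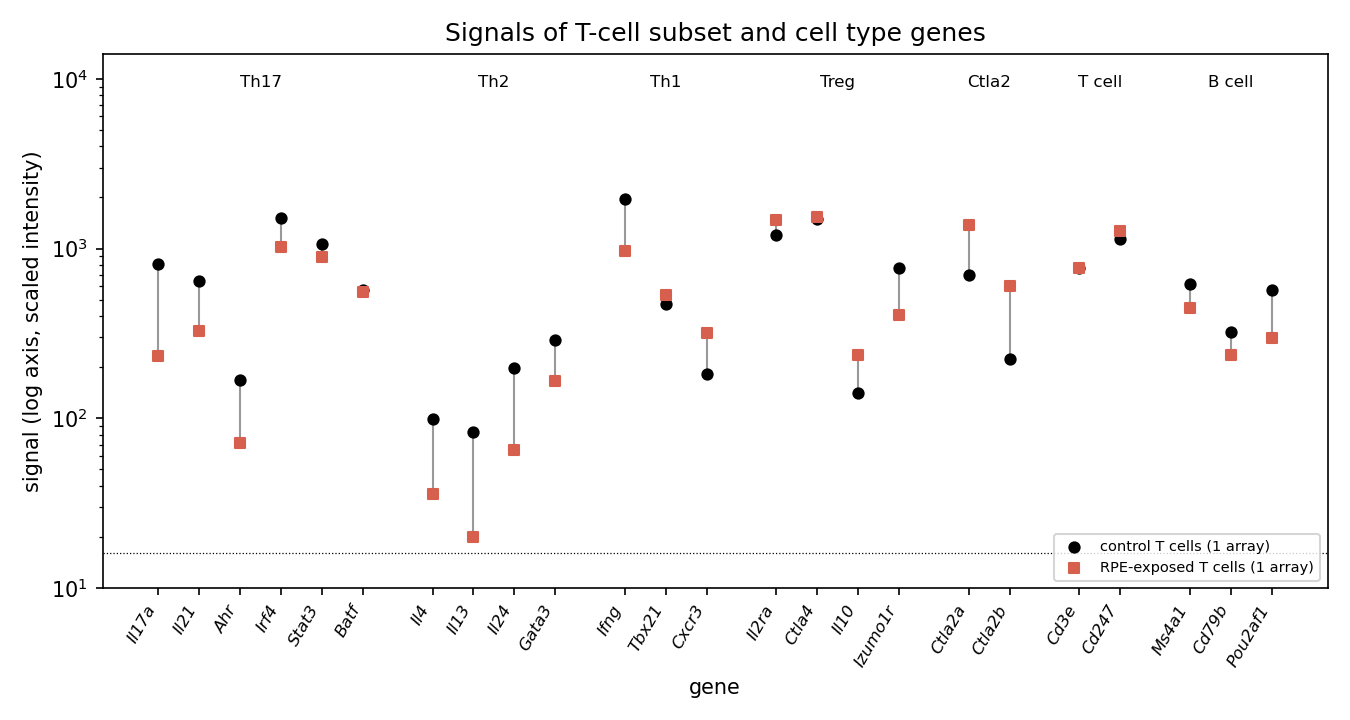
Signal of each gene on a log axis (scaled intensity) in control T cells (black circles) and RPE-exposed T cells (red squares), 1 array each, with the dotted line at the floor of 16. Il17a, Il4, Il13, Il24 and Ifng lie lower after exposure, Ctla2a and Ctla2b higher, and the T-cell genes Cd3e and Cd247 differ little (-0.01 and 0.14). The 3 probe sets of Cd247 above the floor on both arrays gave 0.037 ± 0.099 (SD), and the average over all 4 was -0.24.

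Some cytokine transcripts of the other helper subsets were lower as well. In the Th2 list, Il13 was 4.14-fold lower (83.3 and 20.1, -1.46 with an offset of 16), the chemokine receptor Ccr8 3.09-fold lower (315.6 and 102.1), Il24 3.02-fold lower (196.9 and 65.2) and Il4, the signature Th2 cytokine, 2.80-fold lower (99.6 and 35.6, but -0.14 with the floor at the 75th percentile). Gata3, the Th2 transcription factor, was 1.74-fold lower at 290.4 and 166.6, outside its like-level range of -0.52 to 0.46. Among the other cytokines of the list, Il10 was higher (0.76), and Il5 (-0.45) lay within its like-level range of -0.89 to 0.84. Il3 had a signal of 28.1 in control cells and was under the floor in exposed cells, at least 1.76-fold lower. Il9 was not above the floor on either array. The 4 members Il13, Ccr8, Il24 and Il4 were 2-fold lower, none of the 11 above the floor was 2-fold higher, and the median of -0.80 lay at percentile 0, beside the lower B-cell and macrophage genes given above. With the floor at the 75th percentile (93.1 on the control and 90.4 on the exposed array) the Th2 median was -0.14 at percentile 8.38. Members under that floor on both arrays, such as Il13, Il5 and Ccr4, were then left out.

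In the Th1 list, Ifng, the signature Th1 cytokine, was 2.01-fold lower (1950.0 and 971.4; just under 2-fold, at -0.99, after median centring), and Tnf was at least 5.32-fold lower, with a signal of 85.1 in control cells and under the floor in exposed cells (-1.66 with an offset of 16). Lta, another cytokine of the list, gave -0.35, within its like-level range of -0.75 to 0.65. The Th1 list as a whole did not stand apart (median 0.11, percentile 95.06, 13 members, 2 of them 2-fold lower), but it stood apart as higher in 3 of 9 alternatives, with medians of 0.15 after quantile normalization and 0.19 both with the floor at the 75th percentile and with averaged probe sets. Its receptors Cxcr3 (1.73-fold, 182.4 and 316.3) and Il18r1 (1.84-fold, 70.4 and 129.8) were higher, and Tbx21, the Th1 transcription factor, gave 0.19. Of the follicular helper list, Cxcr5, a receptor that guides T cells and B cells to follicles, was 2.27-fold lower (208.3 and 91.7), in a sample with lower B-cell genes (median -0.54), and the list did not stand apart (median -0.11, percentile 8.71, 10 members). It stood apart as lower in 4 of 9 alternatives, with medians of -0.18 with the floor at the 25th percentile, -0.28 with no floor, -0.16 with averaged probe sets and -0.18 without probe sets ending in x, s or a.

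Regulatory T-cell genes did not stand apart as a list in the main setting. The 20 members had a median of -0.07 at percentile 8.70, with none 2-fold higher and 1 2-fold lower, the orphan receptor Gpr83 (2.14-fold, 70.2 and 32.8, but -0.82 with an offset of 16). Foxp3, the lineage transcription factor, was near the floor, at 18.4 in control cells and under it in exposed cells. Positive differences came from Nrp1 (0.83, signals of 27.9 and 49.5), the anti-inflammatory cytokine Il10 (0.76, 140.6 and 237.3), Prdm1 (0.41), the interleukin-2 receptor chain Il2ra (0.30), Nt5e (0.22), Entpd1 (0.13), Itgae (0.09), the inhibitory receptor Ctla4 (0.05) and Ikzf4 (0.03). Il10 and Nrp1 lay above their like-level ranges of -0.53 to 0.54 and -0.99 to 0.70, but Nrp1 rested on 1 of its 4 probe sets and gave 0.043 when all 4 were averaged. Negative differences came from the folate receptor 4 gene Izumo1r (-0.92), Ebi3 (-0.61), Tnfrsf9 (-0.55), Socs2 (-0.34), Tnfrsf18 (-0.24), Tgfb1 (-0.19), Tnfrsf4 (-0.17), Capg (-0.14) and Ikzf2 (-0.01). Gpr83, Izumo1r, Ebi3, Tnfrsf9 and Tnfrsf18 lay under their like-level ranges, whose lower ends were -0.80, -0.41, -0.59, -0.36 and -0.18. The probe sets of Ikzf2 and of Ikzf4 disagreed in sign. The difference of Ikzf2 changed sign in some settings, median centring and quantile normalization among them, and ran from -0.0079 to 0.15 over 8 alternatives. The list's median moved to -0.18 at percentile 0.18 when all probe sets of a gene were averaged. With the floor at the 75th percentile it moved to -0.17 at percentile 0.09. Over all 9 alternatives it ran from -0.18 to 0.040, at percentiles from 0.09 to 73.7.

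The 2 Ctla2 genes, which encode inhibitors related to the propeptide of cathepsin proteases, were both higher in RPE-exposed T cells. Ctla2b was 2.68-fold higher (224.6 and 602.9) and Ctla2a 1.97-fold higher (697.6 and 1376.0), against like-level ranges of -0.48 to 0.44 and -0.36 to 0.36. They are close paralogs, so their probe sets can share signal and the 2 values are uncertain as separate measurements. The cathepsin genes had values of 0.10 for Ctsb, whose 3 probe sets disagreed in sign, -0.20 for Ctsl and -0.34 for Ctss.

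The list of cathepsin L inhibition and RPE suppression factors that holds these genes went the other way as a whole, with a median of -0.34 at percentile 0 over 21 members, 1 of them 2-fold higher and 2 lower. The lower pair were Ptgs2, the inducible cyclooxygenase (2.85-fold, 68.8 and 24.1, 2 probe sets at -1.54 ± 0.039), and Ido1, a tryptophan-degrading enzyme (2.31-fold, 59.6 and 25.8, but -0.85 with an offset of 16). The costimulatory ligand gene Cd86 (-0.93), Il1rn (-0.89, 3 probe sets at -0.49 ± 0.40), Cd80 (-0.49), Cd274 (-0.47), Serpinf1 (-0.35), Pdcd1lg2 (-0.34), Pomc (-0.30, but 0.12 with averaged probe sets) and Tgfb1 (-0.19) had negative differences. Of these genes only Cd86 lay under its like-level range, and the others lay within theirs. The galectin genes Lgals3 (0.68), Lgals9 (0.15) and Lgals1 (0.13) had positive ones. Tgfb3 lay above the floor in control cells only (24 and 4.8), Ptges was at least 1.28-fold lower, Thbs1 was at least 1.27-fold higher, and Tgfb2 and Vip were not above the floor on either array. With the floor at the 75th percentile the list's median was 0.10 at percentile 94.2, a change of sign. Genes of B cells and antigen-presenting cells, which express several of these members, were also lower in the exposed sample, as given below.

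Activation, NF-kappaB and IL-2 signalling genes were lower in part, in a sample in which B-cell (median -0.54) and macrophage and dendritic-cell genes (median -0.47) were lower too. In the activation list (median -0.17, percentile 0, 19 members), Egr2, an immediate-early transcription factor, was 2.12-fold lower (353.9 and 166.6, 2 probe sets at -0.90 ± 0.27) and Il2, the T-cell growth factor, at least 2.49-fold lower. These were under 2-fold with averaged probe sets (Egr2, -0.90) and with an offset of 16 (Il2, -0.80). Myc gave -0.56, Cd69 -0.47 and Nr4a1 -0.36, while the costimulatory receptor Cd28 gave 0.48. NF-kappaB targets had a median of -0.34 at percentile 0, with 16 of 17 members negative and 2 of them 2-fold lower, Tnf and the chemokine Ccl3 (2.17-fold, 357.0 and 164.5), which antigen-presenting cells also make. The NF-kappaB feedback inhibitor Tnfaip3 was 1.87-fold lower, with 2 probe sets at -0.90 ± 0.0074. IL-2 and STAT5 targets had a median of -0.33 at percentile 0, with 15 of 20 negative and 5 positive. The positive ones included the receptor genes Il2ra (0.30) and Il2rb (0.21), both within their like-level ranges. The list's member Xcl1, a chemokine of activated lymphocytes, was 4.05-fold lower (66.8 and 16.5, -1.35 with an offset of 16), and the STAT5 feedback genes Cish and Socs3 were 1.91-fold and 1.80-fold lower. The exhaustion and anergy list did not stand apart (median 0.0068, percentile 51.2, 16 members), although the orphan nuclear receptor Nr4a3 was 3.43-fold lower (1349.4 and 393.2). The TGF-beta response list lay at 0.0019, percentile 52.97, over 16 members, with Smad7 at -0.18.

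Interferon-response genes were higher together. Of 25 members, 23 had positive differences, and the median of 0.27 lay at percentile 100. The 2 members at least 2-fold higher were the antiviral gene Rsad2 (2.72-fold, 18.5 and 50.3) and Rtp4 (2.24-fold, 70.2 and 157.4), but with averaged probe sets they were under 2-fold, at 0.67 and 0.50. Among bright members, the guanylate-binding protein gene Gbp2 went from 2324.8 to 3169.2 (2 probe sets at 0.41 ± 0.057) and Zbp1, a nucleic acid sensor, from 510.2 to 781.2 (2 probe sets at 0.60 ± 0.015). The negative members were Irf1 (-0.08) and Socs1 (-0.72).

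**Figure D3:**
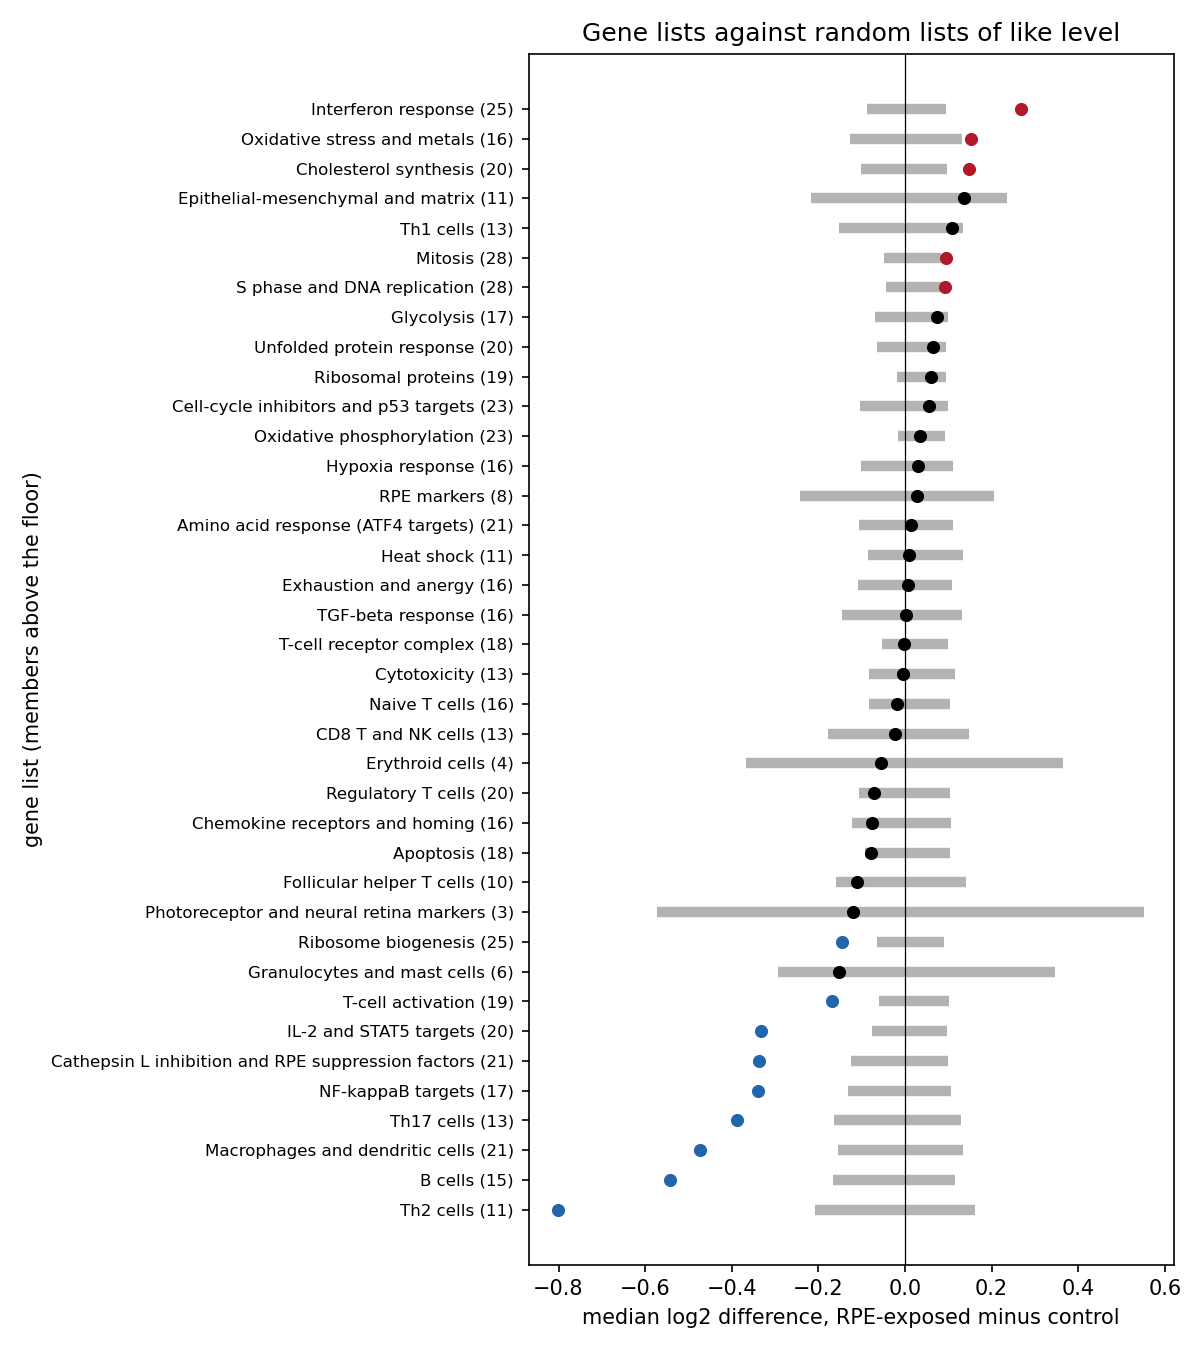
Median log2 difference, RPE-exposed minus control, of each of the 38 fixed gene lists (points, with the number of members above the floor), beside the central 95% of medians of 10000 random lists matched on level (grey bars). Coloured points lie outside the bar, 9 below and 5 above, with the Th2 list lowest at -0.80 and the interferon list highest at 0.27.

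Of the 38 lists, 14 stood apart, 9 lower and 5 higher. About 1.9 would do so if list members varied independently, but they need not, so the number expected by chance is not known. The remaining higher ones moved little. S-phase genes had a median of 0.093 (percentile 98.7, 22 of 28 positive) and mitosis genes 0.094 (percentile 99.0, 22 of 28 positive), with the replication helicase gene Mcm5 at 0.28 ± 0.0053 over 3 probe sets and the mitotic survivin gene Birc5 at 0.37. Cholesterol synthesis genes had a median of 0.15 (percentile 99.8, 17 of 20 positive), with squalene epoxidase, Sqle, at 0.22. Oxidative stress and metal genes had a median of 0.15 (percentile 99.0, 16 members), with glutathione reductase, Gsr, at 0.45. No member of these 4 lists was counted as 2-fold different. Mt1 of the oxidative stress list, above the floor in exposed cells only (12.3 and 31.6), was at least 1.99-fold higher, a lower bound. The mitosis and cholesterol lists were at percentiles 82.5 and 96.3 when all probe sets of a gene were averaged, the oxidative stress list at 95.7 with the floor at the 75th percentile and 90.9 without probe sets ending in x, s or a, and the S-phase list at 97.4 against unmatched random lists. Ribosome biogenesis genes were lower, with a median of -0.15 (percentile 0.01, 18 of 25 negative, none by 2-fold) and the nucleolar gene Gnl3 at -0.27.

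Genes of the T-cell receptor complex list differed little between the samples, and genes of some other cell types were lower. Besides the receptor chains this list holds surface and signalling genes such as Thy1, Cd2, Skap1 and Ptprc. Its 18 genes had a median of -0.0027 (percentile 22.4), with signals of 770.9 and 763.9 for Cd3e. Ptprc, which leukocytes in general express, gave 4083.9 and 4091.7. Naive T-cell genes lay at -0.018 (percentile 24.2, 16 members). B-cell genes were lower, with a median of -0.54 (percentile 0) and 14 of 15 negative. Vpreb3 was 2.40-fold lower (64.4 and 26.8, but -0.91 with an offset of 16), the B-cell surface gene Ms4a1 gave 618.5 and 443.6, and the B-cell coactivator Pou2af1 gave 572.0 and 298.6. Macrophage and dendritic-cell genes had a median of -0.47 (percentile 0) and 17 of 21 negative, with the lysozyme gene Lyz1 at least 2.58-fold lower (but -0.84 with an offset of 16) and the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 at -0.41, -0.62 and -0.63.

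Markers of the RPE itself were mostly undetected in the RPE-exposed sample. Of 28 RPE genes on the array, 8 lay above the floor on at least 1 array. The visual-cycle isomerase Rpe65 had a signal of 5.3 in control and 2.3 in exposed cells, the retinal-binding protein gene Rlbp1 7.0 and 7.5, and the pigment genes Tyrp1 and Dct 9.0 and 3.6, and 12 and 9.3. None of these was above the floor. The 8 above it, among them Ezr and Slc16a1, which T cells also express, had a median of 0.028 (percentile 64.4). Gpnmb, a melanosome protein gene also expressed by macrophages, went from 29.3 to 58.5, a log2 difference of 0.9975, just under 2-fold. Matrix and mesenchymal genes (median 0.14, percentile 87.6, 11 members, but percentile 97.9 with averaged probe sets), photoreceptor genes (-0.12, percentile 39.5, 3 members), granulocyte and mast-cell genes (-0.15, percentile 13.9, 6 members), CD8 T-cell and NK-cell genes (-0.023, percentile 42.4, 13 members) and erythroid genes (-0.055, percentile 40.5, 4 members, but percentile 99.75 with no floor) did not stand apart. Within the matrix list the intermediate filament gene Vim went from 1799.7 to 2885.1 (3 probe sets at 0.62 ± 0.063), and within the CD8 and NK list the adhesion receptor Crtam was 2.12-fold lower, but -0.39 with the floor at the 75th percentile and -0.91 with an offset of 16.

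Among genes above the floor on both arrays, the lowest was Tcl1b3, a member of a family of near-identical genes, 5.503-fold lower (1172.2 and 213.0) on a probe set shared with other sequences. Tgm2, a transglutaminase, was 4.87-fold lower (815.7 and 167.4), and its 5 probe sets above the floor gave -2.01 ± 0.27 (SD), but the average over all its probe sets was -1.24. Adamtsl4 was 3.19-fold lower (216.1 and 67.8), and Csf2, the gene of the cytokine GM-CSF, 3.17-fold lower (101.8 and 32.1), which was -0.17 with the floor at the 75th percentile. The highest was H1f2, a linker histone gene, 3.56-fold higher (73.7 and 262.4, 2 probe sets above the floor at 1.75 ± 0.12, but 1.24 over all its probe sets). Tank, an adaptor of TRAF signalling, was 3.52-fold higher on one probe set (114.0 and 401.5), but its other probe set gave a negative difference, -0.15. Atp5md, a subunit of ATP synthase, was 2.82-fold higher (319.7 and 900.7), the selenoprotein gene Selenow 2.58-fold higher (2 probe sets at 1.23 ± 0.19) and the membrane protein gene Emp1 2.501-fold higher (72.6 and 181.6, but 0.96 with the floor at the 75th percentile). The dimmer genes 4930486L24Rik, Crmp1 and Fbxw22 were 2.57-fold, 2.53-fold and 2.498-fold higher, but Crmp1 gave 0.87 with an offset of 16 and Fbxw22 0.14 with the floor at the 75th percentile. The bounds upward were at least 3.43-fold for Slco2b1, 3.11-fold for Cdc42bpa, 3-fold for Tmem63b, 2.83-fold for Aif1l and 2.71-fold for Mark1, all with exposed signals under 60. With an offset of 16 their differences ran from 0.89 (Mark1) to 1.15 (Slco2b1). Aif1l had another probe set above the floor on both arrays, with a smaller difference of 0.49, and the other 4 genes had further probe sets, none of them above the floor on both arrays. Downward they were largest for Tnf and Lyz1, followed by at least 2.53-fold for Ccl6, 2.49-fold for Il2 and 2.21-fold for Ss18l1. Ccl6 gave -0.50 with averaged probe sets and Ss18l1 -0.68 with an offset of 16.

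The remaining lists did not stand apart, and the medians of cytotoxicity, the amino acid response, oxidative phosphorylation and the T-cell receptor complex changed sign between scalings. Their medians were -0.0045 for cytotoxicity (percentile 31.2, 13 members, with the granzyme gene Gzmb at 5632.9 and 6096.3), -0.076 for chemokine receptors and homing (percentile 11.8, 16 members), -0.078 for apoptosis (percentile 4.8, but 2.37 with the floor at the 25th percentile) and 0.056 for cell-cycle inhibitors and p53 targets (percentile 87.0). The metabolic lists lay at 0.074 for glycolysis (percentile 90.6, with lactate dehydrogenase, Ldha, at 0.09), 0.030 for hypoxia (percentile 66.7), 0.036 for oxidative phosphorylation (percentile 50.5) and 0.014 for the amino acid response (percentile 55.6). The unfolded protein response lay at 0.066 (percentile 90.1, but 99.3 with averaged probe sets), heat shock at 0.0092 (percentile 36.5) and ribosomal proteins at 0.059 (percentile 77.8).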

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

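The signals and tests in this part were chosen after the results had been seen, apart from the gene lists, which were fixed before. Outside the gene comparisons, 14 of the 3589 detected probe sets with no gene name or several names were at least 2-fold higher in RPE-exposed T cells, and 30 were 2-fold lower. Only 1 of the higher and 9 of the lower ones reached a signal of 100. Of those above the floor on both arrays, the highest had no listed gene (19.7 and 51.6, log2 difference 1.39), and the lowest was assigned several genes (98.2 and 31.3, log2 difference -1.65).

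In a set of 16 cytokine genes drawn up after their values were seen (Il2, Il3, Il4, Il5, Il6, Il9, Il10, Il13, Il17a, Il21, Il24, Ifng, Tnf, Lta, Lif and Osm), 15 were above the floor, 14 of these had negative differences, 7 were at least 2-fold lower, Il10 was the exception at 0.76, and the median was -0.98, a value that the choice of the set itself can lower. A smaller share of T-cell RNA, from fewer T cells or from RPE carried along, would lower the genes of the T-cell receptor complex list alike. Their median was -0.0027 (95% interval over members -0.059 to 0.16). Most of these genes are expressed by CD8 T cells too, so they cannot show a smaller share of CD4 cells among the T cells. Fewer dividing cells would lower cell-cycle genes, whose median was 0.094 (0.060 to 0.12 over 56 genes). Lost RNA of fewer B cells and antigen-presenting cells, which make some of these cytokines, weaker stimulation because fewer antigen-presenting cells were there, an effect of the RPE on the T cells, and chance differences between 2 single cultures stay open and were not tested.

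B-cell and antigen-presenting-cell transcripts were lower in 31 of 36 markers, with a median of -0.49, and 13 of the 36 lay under the range of genes of like level. Of the 12 most abundant markers 8 lay under that range and 4 within it, among them Ighm (2794.6 and 2758.9 on its brightest probe set, with 8 probe sets at -0.52 ± 0.51 (SD) that disagreed in sign), Cd74 (-0.21) and Iglv1 (-0.20). The median lay at percentile 0 of random lists of genes of like level, whose central 95% ran from -0.11 to 0.083. Genes of like level thus did not share the difference. The pattern was picked by this same kind of percentile, so it is no separate test of a level-dependent difference between the arrays. A smaller share of these cells and lower transcript levels in each such cell both stay open as candidate explanations, and no value here separates them.

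Interferon-response transcripts were higher in 23 of 25 members. Their median of 0.27 lay at percentile 100 of random lists of genes of like level (central 95% from -0.087 to 0.093). The list was picked by this percentile, so it is no separate test of level-dependent scaling. A larger share of T cells would raise the genes of the T-cell receptor complex list alike, but their median was -0.0027 (95% interval over members -0.059 to 0.16). The interferon median lay above theirs by 0.27 (95% interval over members 0.087 to 0.49). As the interferon list was picked for its high median, this difference is no separate test. Such intervals treat members as independent and hold no variation between cultures. More interferon-gamma transcript at harvest is argued against by Ifng itself, at a log2 difference of -1.005. Other interferons, earlier signalling and chance differences between 2 single cultures stay open, and whether RPE exposure is the source was not tested.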

How the results depend on the processing

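No paired analysis was possible because each group had 1 array, and no replicate could be left out. The counts of 2-fold genes (48 higher, 69 lower) stayed within 1.5 times under median centring, quantile normalization, averaged probe sets, the suffix filter and the demand that every probe set move, with 36 to 62 higher and 59 to 95 lower. They became 659 and 578 with the floor at the 25th percentile, 6 and 16 at the 75th, 1741 and 1592 without a floor, 15 and 23 with an offset of 16, 344 and 426 at 1.5-fold, and 5 and 11 at 3-fold. Signals near the floor therefore set most of these counts. Among the 14 lists that stood apart and the regulatory T-cell list, 126 of 135 alternatives kept the same side of the band. With the floor at the 75th percentile, the median of the cathepsin L inhibition and RPE suppression factors reversed to 0.10, and those of Th2 (-0.14), oxidative stress (0.12) and regulatory T cells (-0.17) crossed the band. Averaged probe sets moved regulatory T cells to -0.18, mitosis to 0.044 and cholesterol synthesis to 0.099 across it, and the suffix filter moved oxidative stress to 0.11. Unmatched random lists put S phase (0.093) at percentile 97.4. Fewer members pass a higher floor, and the cause of the other moves was not tested. The Th17 median ran from -0.54 to -0.32 and the interferon median from 0.20 to 0.31 over 9 alternatives. Of the other lists, 192 of 203 alternatives kept their side, and 7 of the 11 that did not were of the Th1 and follicular helper lists. Among genes, Tank reversed to -0.15 under the suffix filter, which leaves its other probe set. Averaged probe sets turned the sign of 6 genes that were under 2-fold, by more than 0.24: Maf (-0.32), Cd247 (-0.24), Cd4 (0.26), Ikzf4 (-0.44), Pomc (0.12) and Slc16a1 (-0.41). The suffix filter did so for Iglv1 (0.29). Of 45 named genes that differed by 2-fold, 22 were under 2-fold in at least 1 alternative. With the floor at the 75th percentile these were Ahr, Crtam, Csf2, Emp1, Fbxw22, Il4 and Rtp4, with averaged probe sets Ccl6, Egr2, Rsad2, Rtp4 and Tank, under the suffix filter Tank, and after median centring Ifng. With an offset of 16, which shrinks dim signals most, there were 14: Aif1l, Ccl6, Crmp1, Crtam, Gpr83, Ido1, Ifng, Il2, Lyz1, Mark1, Rsad2, Ss18l1, Tmem63b and Vpreb3. A lower floor or none raised the bounds of genes above the floor on 1 array, as for Tnf (to -3.31). Il17a ran from -1.81 to -1.74, and 967 of 1056 alternatives moved a named gene by less than the probe-set SD of 0.24. Median centring shifted every gene by 0.011 on the log2 scale, and quantile normalization shifted the median gene by 0.016 but single genes further (Gzma from 0.15 to 0.094).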

Other observations

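The samples held transcripts of cytotoxic lymphocytes beside those of CD4 T cells, although the control was titled as CD4 T cells. Cd8a had a signal of 568.8 in control and 694.6 in exposed cells, and Cd8b1 706.4 and 983.9, although the 5 probe sets of Cd8a disagreed in the sign of the difference. The granzyme gene Gzma stood at 3714.7 and 4122.5, and the NK-cell receptor gene Klrd1 at 600.1 and 590.6. Cd4 gave 287.0 and 271.1, with its 2 probe sets of opposite sign. Signals of different probe sets cannot be set against each other as amounts, so these values give no share of CD8 cells.

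The following genes were not taken by the naming rule and were chosen after their values were seen. Myo6, an actin-based motor gene that ranked just outside the 10 lowest, went from 2085.2 to 722.3, and its 3 probe sets gave -1.89 ± 0.69 (SD). Ccl22, a chemokine made by activated antigen-presenting cells, was 2.36-fold lower (311.6 and 132.1), and Ecm1, an extracellular matrix protein gene expressed by Th2 cells, was 2.33-fold lower (1660.9 and 713.3). Igfbp4, a member of the naive T-cell list, was 1.90-fold lower, with 5 probe sets at -0.77 ± 0.34 (SD). The interferon-inducible gene Xaf1 was 1.99-fold higher (159.8 and 317.9).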
